A study of Mus musculus with 9 samples.

How the data were processed

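Liver RNA of C57BL/6J mice was measured in 9 libraries, 3 from each of 3 groups. Per the labels, the mice were gavaged for 8 weeks with distilled water (Control), with 1500 mg/kg/d of the plasticizer di(2-ethylhexyl) phthalate in corn oil (DEHP), or with the same dose plus 70 mg/kg green tea polyphenols (DEHP_GTP). Groups given corn oil alone or the polyphenols alone belong to the design but were not analysed here, so the phthalate and its oil vehicle were not separated. Group and replicate number were taken from the sample titles. The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

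Per the labels' protocols, messenger RNA was selected on oligo(dT) beads, fragmented and reverse transcribed with random hexamers, and the products were circularized. The submitters' processing notes name the mouse build mm9, CASAVA 1.7 and limma, without their roles. The aligner, the counting tool and the annotation are not given in the sources used here. The deposited table gave 1 non-negative signal per gene symbol and library, with 2 decimals, for 18148 symbols. From the values it was of the FPKM or TPM kind, scaled by the authors for depth and transcript length, but which of these was not stated. Library totals ran from 789076 to 863300, and the DEHP_GTP libraries had the lowest. Means were 845003 ± 22092 in Control, 843344 ± 28596 in DEHP and 796639 ± 6607 in DEHP_GTP libraries (SD, n = 3). Of the symbols, 18078 (99.6%) matched RefSeq names of GRCm38.p6, and since the builds differ no coordinates are given.

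Absolute depth is unknown. Low genes, at 0 in at least 2 libraries, moved in steps: 79.0% of 687 values in 143 genes lay within 0.1 of a whole multiple, against 49.2% after random jitter of the values. By these steps, the estimates of what 1 read was worth ranged over 8.73% between libraries. The estimate started from equal libraries and used only values near whole multiples, so larger differences in depth could be missed. Similar depth was therefore not shown, and no interval based on read counts could be given.

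Values were tested as log2(value + 1), a scale that understates changes of low genes. Genes with a value of at least 1 in at least 3 libraries were kept, which left 10388 genes; 1212 symbols were at 0 throughout. One limma model (version 3.58.1, R 4.3.3, with trend and robust variance estimates) was fitted to all 9 libraries, so that the 3 groups shared 1 estimate of spread. Each of the 3 comparisons was adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p below 0.05. Of 41 gene lists fixed before the data were examined, the 35 with at least 5 tested members were tested with camera, using a preset correlation of 0.01 between genes and again with an estimated correlation, and with fry.

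Named genes followed a rule fixed at the same time. It took the 6 largest rises and 6 largest falls among called genes whose libraries did not overlap and whose higher group averaged at least 5, leaving out provisional symbols. It added up to 3 called genes with the smallest adjusted p from each list and 12 liver genes chosen in advance, some of which are not reported here. Where too few genes passed, the 5 with the smallest unadjusted p were given as not passed. Genes named outside the rule are said to be so.

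Quantile normalization, no filter on low values, limma without trend and robust estimates, a pseudocount of 0.1, only the 6 libraries compared, a replicate block, a fold threshold and leaving out each library were planned as alternatives. Rescaling every library to the same total, centring on the median gene, rescaling without the Mup genes, adjusting over the genes called under DEHP, and using Control replicate 3 as the lone control were added after the data had been seen. The code was tested on simulated data of 10388 genes. For DEHP against Control it recovered 55.9% of 68 genes changed by 0.5 on the log2 scale, 81.8% of 66 changed by 1 and 100% of 66 changed by 2, with 4 false calls. For DEHP_GTP against DEHP it recovered 57.4%, 84.8% and 100% of the same genes, with 13 false calls.

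Values of near-identical gene copies (the Mup, Serpina1, Cyp2a, Cyp2b, Cyp4a and Hamp families) are uncertain, because how reads were split between copies is not given in the sources used here.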

Results

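Messenger RNA was profiled in 9 mouse liver libraries, 3 each from mice given water (Control), the plasticizer di(2-ethylhexyl) phthalate in corn oil (DEHP), or the phthalate with green tea polyphenols (DEHP_GTP). The series title names the question of whether the polyphenols lessen liver injury from the phthalate. The first principal component held 55.2% of the variance. The 3 Control libraries lay between -27.0 and -25.8 on it, the 3 DEHP libraries between 13.02 and 28.57, and the 3 DEHP_GTP libraries between -3.46 and 13.9.

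The Control libraries were not alike in transcripts typical of fat tissue. Adipoq, the fat cell hormone adiponectin, was at 33.7 in Control replicate 1 and 61.0 in Control replicate 2 and was listed at 0 in the other 7 libraries. Ucp1, the uncoupling protein of brown fat, was at 50.3 and 36.2 in those same libraries and was listed at 0 elsewhere, and Cox8b was at 128.51 and 126.84 there and at most 0.65 elsewhere. In all, 33 genes were over 2-fold above every other library in this pair, against at most 4 genes in any other of the 36 pairs of libraries. Adipoq, Plin1 and Retn belong to the list of adipocyte markers, but like Ucp1 and Cox8b they were chosen after their values were seen. Other members of that list, named outside the rule, set the pair apart less clearly. Fabp4 was at 470.21 and 688.64 in the pair and at 361.68 in DEHP replicate 1. Adrb3 was at 3.82 and 5.46 against 5.5 in DEHP replicate 3, and Car3 at 2690.43 and 2690.49 against 2147.22 in DEHP_GTP replicate 1. Adipoq, Plin1, Retn, Ucp1 and Cox8b did not reach the filter of 3 libraries and so were not among the genes tested. Cfd, Cidec and Cidea, also named outside the rule, were tested. In Control replicates 1 and 2 Cfd was at 221.03 and 491.14, Cidec at 31.24 and 58.55, and Cidea at 26.76 and 29.95. Elsewhere they were at most 1.15, 1.76 and 5.33. Cidec and Cidea also belong to the later list of targets of the nuclear receptor PPARA.

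**Figure D1:**
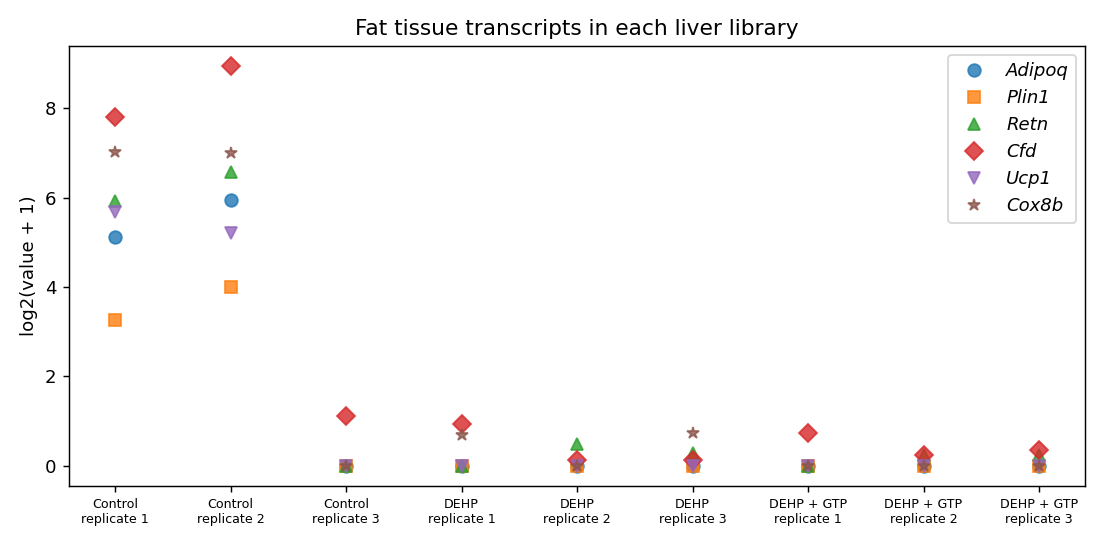
Deposited values of 6 fat tissue genes as log2(value + 1) on the vertical axis, 1 point per gene in each of the 9 liver libraries. The points of Control replicates 1 and 2 stand above those of the other 7 libraries, with Adipoq at 33.7 and 61.0 before the log scale against 0 elsewhere.

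DEHP against Control asked what the phthalate in its oil did to liver transcripts. Genes of fatty acid oxidation were among the largest rises. Cyp4a14 and Cyp4a10, fatty acid omega-hydroxylases induced through the nuclear receptor PPARA, went from 116.7 ± 25.99 to 4330 ± 1203 and from 175.7 ± 29.95 to 4098 ± 1286 (SD, n = 3). Ehhadh, a peroxisomal beta-oxidation enzyme, rose by 4.92 on the log2 scale (SE 0.37). Mup7, a major urinary protein, and Hsd3b5, a steroid dehydrogenase typical of male liver, fell by 7.05 (SE 1.65) and 4.61 (SE 1.29), calls that were lost in 6 and 11 of 18 other settings. Values of near-identical copies, among them the Mup, Cyp2b and Cyp4a genes, are uncertain.

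With limma, 2654 of 10388 genes changed, 2248 higher and 406 lower, and 274 changed at least 2-fold. The median gene lay 0.12 above 0 on the log2 scale, and the split between higher and lower depended on scaling. It was 1928 and 330 after rescaling to equal totals, 922 and 833 after quantile normalization, 1271 and 736 after centring on the median gene, and 809 and 1003 after rescaling without the Mup genes. The Mup genes held 18.8% ± 2.36 of the total in Control libraries and 5.49% ± 3.06 in DEHP libraries (SD, n = 3). Without Control replicate 1 the count was 1703. Control replicate 3, the Control library with Adipoq, Plin1 and Ucp1 listed at 0, was also used as the lone control. In that fit the median gene lay 0.18 above 0 on the log2 scale. That fit assumes that the lone library varies like the other groups.

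Of 58 tested PPARA targets of fatty acid oxidation, 42 rose and 0 fell, or 45 and 3 adjusted over the list alone. Camera placed the list above other genes, with an adjusted p of 1.31e-11 at the preset correlation and an adjusted p = 0.649 with an estimated correlation. At the preset correlation camera called 16 of 35 lists, and 3 of the 10 splits of these 6 libraries, the real one included, gave as many. The other splits keep part of the difference between the groups, so they do not show what unchanged groups would give. Cpt1a, which carries fatty acids into mitochondria, had a log2 fold change of -0.24 (SE 0.09) and an adjusted p of 0.0652, and Pdk4 one of 0.21 (SE 0.46), so neither passed in the main fit. Cpt1a was called in 4 of the 18 other settings. Pdk4 was called with the lone control, at 1.14 (SE 0.24, adjusted p = 0.0385), and in no other setting. With the lone control 30 members were higher and 0 lower.

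Of 41 tested targets of the xenobiotic receptors CAR and PXR, 22 rose and 2 fell, or 22 and 3 adjusted over the list alone, with an adjusted p = 0.307 with an estimated correlation. Cyp2b9, which had the largest rise by the rule, went from 0.457 ± 0.371 to 211 ± 75.9, and Cyp2b10 from 14.9 ± 6.97 to 108 ± 26.6 (SD, n = 3). Among 35 tested NRF2 targets, 24 rose and 1 fell, or 29 and 1 adjusted over the list alone, and the adjusted p = 0.649 with an estimated correlation. Gsta2, a glutathione transferase, rose by 1.44 (SE 0.13), Ugdh by 1.23 (SE 0.14) and Nqo1 by 1.11 (SE 0.23). The lists share members, so their counts are not independent. Gsta2 is also in the CAR and PXR list, and Cyp2b9 and Cyp2b10 are also in the list of female-biased genes.

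Of 26 genes of cholesterol synthesis, 14 rose and 0 fell, or 18 and 0 adjusted over the list alone, with an adjusted p = 0.706 with an estimated correlation. Tm7sf2 rose by 0.83 (SE 0.11) and Cyp51 by 1.08 (SE 0.16). Of 31 oxidative phosphorylation genes, 27 rose and 0 fell, or 30 and 0 adjusted over the list alone, with an adjusted p = 0.654 with an estimated correlation. Of 33 ribosomal protein genes, 25 rose and 0 fell, or 28 and 0 adjusted over the list alone, with an adjusted p = 0.656 with an estimated correlation. These last lists moved with the scaling: after quantile normalization 6 oxidative phosphorylation genes and 1 ribosomal protein gene were called higher. Across genes, fold changes also fell with transcript length (Spearman correlation -0.248), and whether this moved these lists was not tested.

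Of 30 genes with higher expression in male liver, 17 fell and 2 rose, or 21 and 4 adjusted over the list alone, with an adjusted p = 0.586 with an estimated correlation. Egfr, the epidermal growth factor receptor, fell by 1.35 (SE 0.18), and Selenbp2 by 4.58 (SE 0.97). The members that rose were Cyp4a12a by 1.47 (SE 0.14) and Cyp4a12b by 2.20 (SE 0.22), which are omega-hydroxylases. Of 20 female-biased genes, 6 rose and 1 fell, or 7 and 2 adjusted over the list alone, and camera did not call the list (adjusted p = 0.483), while fry did (adjusted p = 0.0213). Its member that fell was Fmo2, a flavin monooxygenase, by 1.25 (SE 0.20). Of 18 other settings, the calls of Mup15, Mup11 and Hsd3b5 were lost in 14, 13 and 11, those of Mup7, Cyp2a4 and Selenbp2 in 6, 5 and 4, and with the lone control 4 male-biased genes were called lower.

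Of 38 complement and coagulation genes, 10 fell and 5 rose, the same counts adjusted over the list alone, with an adjusted p = 0.586 with an estimated correlation. C8b and C9, parts of the membrane attack complex, fell by 1.21 (SE 0.18) and 1.18 (SE 0.20). Of 18 circadian clock genes, 10 fell and 3 rose, or 12 and 4 adjusted over the list alone, with an adjusted p = 0.307 with an estimated correlation. Per3, a period gene, fell by 1.27 (SE 0.15), and Nr1d1, a clock repressor, rose from 15.4 ± 2.14 to 53.8 ± 16.5 (SD, n = 3). Of 5 tested adipocyte markers, 0 were called, also adjusted over the list alone, and camera placed the list below other genes, with an adjusted p = 0.654 with an estimated correlation. That list holds Cfd and Cidec, which were high only in Control replicates 1 and 2. Camera at the preset correlation also placed red blood cell markers below other genes (median -0.60, adjusted p = 0.0415). The same held for pericentral hepatocyte markers (median -0.05, adjusted p = 0.0333). Both had an adjusted p = 0.706 with an estimated correlation.

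**Figure D2:**
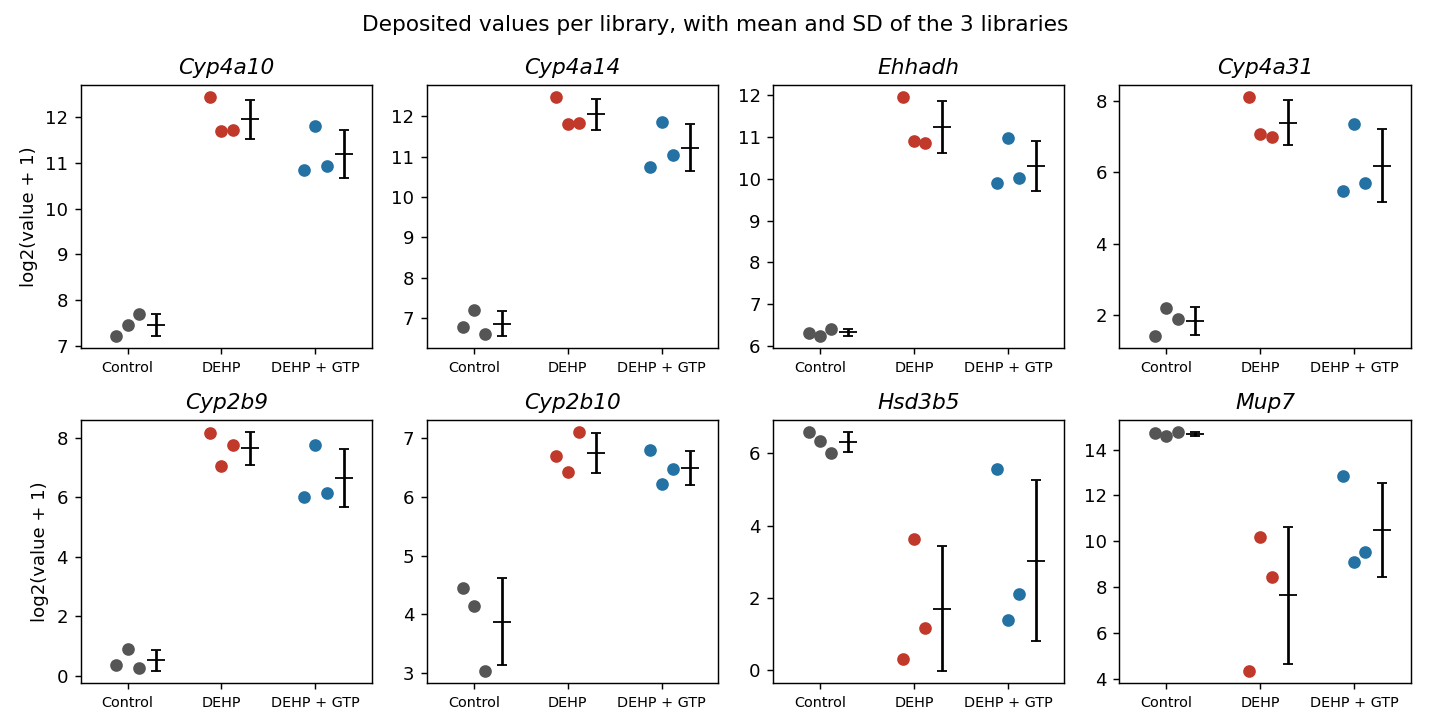
Values of 8 named genes as log2(value + 1) on the vertical axes, 1 point per library in the Control, DEHP and DEHP_GTP groups, with the mean and SD of 3 libraries beside the points. Cyp4a10, Cyp4a14, Ehhadh and Cyp4a31 were above every Control library in all 3 DEHP libraries, and vertical axes do not start at 0.

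DEHP_GTP against DEHP asked what the polyphenols changed in mice given the phthalate. No gene passed: limma called 0 of 10388 genes, with a smallest adjusted p of 0.0761. Limma without trend and robust estimates also called 0, and 1524 genes (14.7%) had an unadjusted p below 0.05. The 5 genes with the smallest unadjusted p were Nuak2 at 0.71 (SE 0.09), P2ry2 at 0.59 (SE 0.09), Per3 at 1.03 (SE 0.15), Pcsk4 at 0.61 (SE 0.09) and Marveld1 at 0.59 (SE 0.09) on the log2 scale. Among genes chosen in advance, Cyp4a14 was at -0.83 (SE 0.31, adjusted p = 0.283) and Cyp2b10 was at -0.25 (SE 0.37, adjusted p = 0.805).

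The PPARA target list had a median of -0.41, and 2 of its 58 members were above 0, with 0 called over all genes and 1 lower adjusted over the list alone. Camera placed it below other genes (adjusted p = 6.05e-14), with an adjusted p = 0.695 with an estimated correlation. At the preset correlation 12 lists were called, and 9 of the 10 splits of these 6 libraries, the real one included, gave as many. Here too the other splits keep part of any difference between the groups. Endothelial cell markers were among the 12, with a median of -0.19 and 1 of 19 above 0 (camera adjusted p = 0.00566). So were periportal hepatocyte markers, with a median of 0.12 and 14 of 17 above 0 (camera adjusted p = 0.0188). Both had an adjusted p = 0.801 with an estimated correlation. For circadian clock genes the median was 0.37, with 10 higher and 3 lower adjusted over the list alone, and an adjusted p = 0.474 with an estimated correlation. For NRF2 targets the median was -0.31, with 1 higher and 12 lower adjusted over the list alone, and camera gave an adjusted p of 6.91e-08 at the preset correlation and an adjusted p = 0.695 with an estimated correlation. Fry, which tests whether a list moves on balance one way, called 0 of the 35 lists, and its mixed test, for change in either direction, called 9. In DEHP against Control fry called 15 and its mixed test 27, and in DEHP_GTP against Control 9 and 24. Without DEHP replicate 2 the count of called genes was 86, without DEHP_GTP replicate 3 it was 7 and without DEHP replicate 1 it was 5. Rescaling without the Mup genes gave 35.

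Of the 2248 genes that rose under DEHP, 2019 (89.8%) had an opposite fold change in DEHP_GTP against DEHP, and of the 406 that fell, 391 (96.3%) did. These genes were selected for their change in the shared DEHP libraries, which raises both shares. Over all 10388 genes 70.6% had opposite signs, against a mean of 66.3% in simulations of unchanged groups. Without DEHP replicate 1, 2 or 3 the share was 71.3%, 73.6% or 71.0%, each against a simulated 71.2%. There the observed share did not fall but the simulated share rose, so without DEHP replicate 1 or 3 little or no excess was left. Without DEHP_GTP replicate 1, 2 or 3 the share was 66.3%, 71.2% or 69.7%, each against a simulated 64.5%. No gene was called in both comparisons with opposite signs. Both comparisons use the DEHP libraries, and a shared group gives fold changes of opposite sign without any effect. Across genes, which are not independent replicates, the covariance of the log2 fold changes was -0.0726, against a mean of -0.0131 and a lowest of -0.0374 in 100 such simulations. The correlation was -0.698, within the simulated range, which had a mean of -0.468 and a lowest of -1. The simulations reuse the deviations of libraries from their group means, and a correlation of -1 arises where these cancel. That lowest value therefore cannot decide whether the observed correlation was unusual. With 3 DEHP libraries no split could leave 2 in each part, so part of the excess may come from the shared libraries.

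DEHP_GTP against Control asked what remained different with both treatments. Of the 6 largest rises, 5 were also among the 6 largest under DEHP alone. Cyp2b9 rose by 6.14 (SE 0.51), Cyp4a14 by 4.36 (SE 0.31), Ehhadh by 3.99 (SE 0.37) and Cyp4a10 by 3.75 (SE 0.30). Hamp2, a hepcidin gene, rose by 3.15 (SE 0.33). Serpina12, the adipokine vaspin, fell by 3.10 (SE 0.19), Enho, which encodes adropin, by 1.64 (SE 0.17), and G0s2, an inhibitor of triglyceride lipase, by 1.39 (SE 0.19). With Control replicate 3 as the lone control, the calls of Cyp2b9, Ehhadh, Cyp4a10, Hamp2 and G0s2 were lost, and those of Cyp4a14, Serpina12 and Enho were kept. The log2 fold changes of the lost calls were then 6.40 for Cyp2b9, 3.90 for Ehhadh, 3.50 for Cyp4a10, 2.62 for Hamp2 and -1.54 for G0s2.

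With limma, 1085 genes changed, 1006 higher and 79 lower, and 93 changed at least 2-fold. The split was 1953 and 71 after rescaling to equal totals, 172 and 110 after quantile normalization, 180 and 96 after centring on the median gene, and 296 and 62 after rescaling without the Mup genes. The count moved with single libraries. It was 279, 471 and 277 without Control replicates 1, 2 and 3, 254 without DEHP_GTP replicate 2 and 382 without DEHP_GTP replicate 3, and with Control replicate 3 as the lone control it was 10. There the lone library was assumed to vary like the other groups, and fold changes moved by different amounts. Among calls that were lost, Cyp4a10 went from 3.75 to 3.50 (SE 0.44) and Ehhadh from 3.99 to 3.90 (SE 0.57). Scd1 went from 1.56 to 1.02 and Creld2 from -1.17 to -0.67. Other lost calls had larger fold changes there: Apoa4 went from -1.26 to -1.34 and Colec10 from 0.43 to 0.51. Cyp2b10, still called, went from 2.62 to 3.46, and Pdk4, called in neither fit, from -0.61 to 0.32. The median over all genes was 0.17 against 0.11.

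Of 58 PPARA targets, 28 rose and 0 fell, or 37 and 1 adjusted over the list alone, with an adjusted p = 0.564 with an estimated correlation. Of 41 CAR and PXR targets, 16 rose and 0 fell, or 23 and 0 adjusted over the list alone, with an adjusted p = 0.508 with an estimated correlation. Aldh1a7 rose by 0.71 (SE 0.09) and Cyp3a13 by 0.61 (SE 0.08). Of 35 NRF2 targets, 9 rose and 1 fell, or 17 and 1 adjusted over the list alone, with an adjusted p = 0.564 with an estimated correlation. The member that fell was Gstp1, by 1.01 (SE 0.16). Of 30 male-biased genes, 4 fell and 2 rose, or 7 and 2 adjusted over the list alone, with an adjusted p = 0.564 with an estimated correlation. Hsd3b5 was at -3.29 (SE 1.29, adjusted p = 0.154) and did not pass. Camera at the preset correlation also placed markers of other cells below other genes, with 0 members called in each list: endothelial cells (median -0.17, adjusted p = 1.57e-06), adipocytes (-1.95, 0.00264) and red blood cells (-0.73, 0.00253). Each had an adjusted p = 0.564 with an estimated correlation, and fry called none of them.

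Of the genes called under DEHP, 858 higher and 70 lower genes were called the same way in DEHP_GTP against Control. Independent lists would share 218 and 3.09. Unchanged groups simulated against the same controls shared 0, but a mean of 0.24 and 0.17 genes were called there, so this count does not measure what shared controls add. The covariance of the fold changes across genes was 0.127, against a simulated mean of 0.0130 and a highest of 0.0381, and the correlation was 0.863, within the simulated range that reached 0.936. With 3 Control libraries no split could leave 2 in each part, so part of the overlap may come from the shared controls. Whether the response to the phthalate differed in size between the treated groups is what DEHP_GTP against DEHP tested, and no gene passed there.

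**Figure D3:**
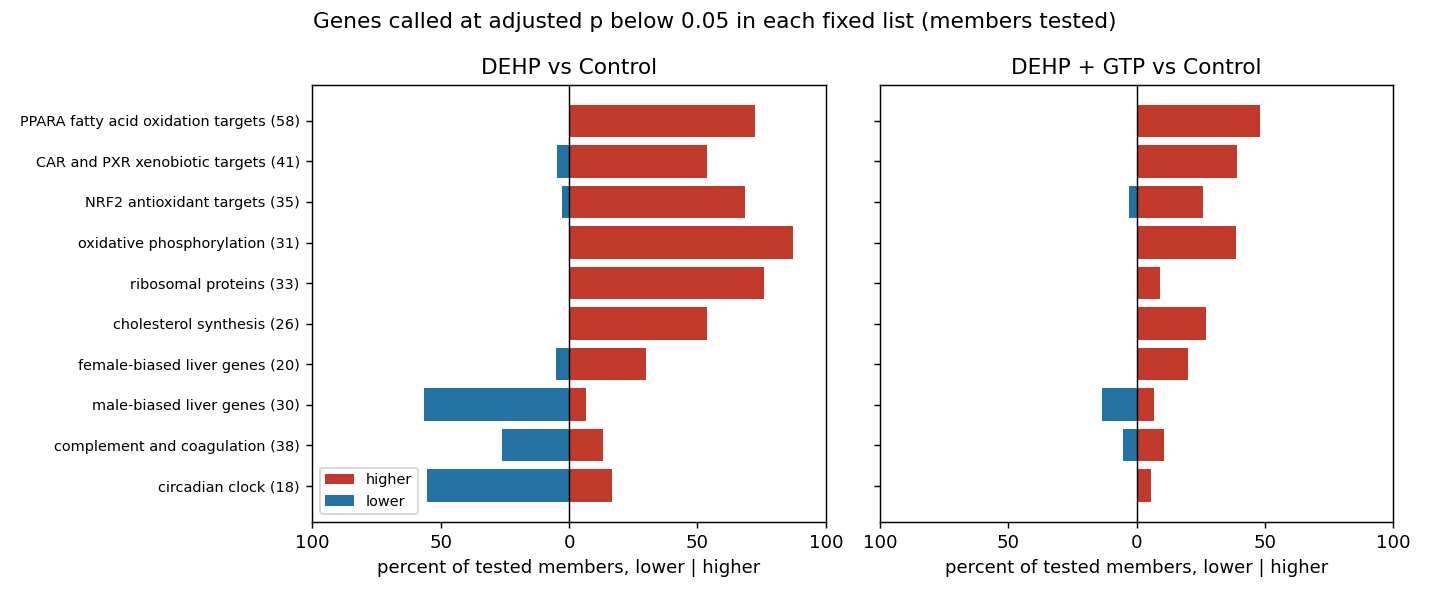
Percent of tested members called higher (right of 0) or lower (left of 0) in 10 fixed gene lists, for DEHP against Control and DEHP_GTP against Control, with the number of tested members in parentheses. For PPARA targets the bars stand for 42 and 28 of 58 genes.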

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

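The scalings, the adjustment over genes called under DEHP and the lone control were chosen after the data had been seen. Genes changed in DEHP against Control numbered 1755 after quantile normalization (1301 of them among the 2654), 274 with a fold threshold of 1 on the log2 scale, 757 with the lone control, and 1703 to 2727 with 1 library left out. Genes changed in DEHP_GTP against DEHP numbered 1 without the filter, 1 with only the 6 libraries, 5 after rescaling to equal totals, 35 after rescaling without the Mup genes, 1 with the lone control, 237 adjusted over the genes called under DEHP, which is not independent evidence, and 0 to 86 with 1 library left out. Genes changed in DEHP_GTP against Control numbered 282 after quantile normalization, 582 without the filter, 93 with the fold threshold, 2024 after rescaling to equal totals, 276 after centring, 358 without the Mup genes, 10 with the lone control, and 254 to 1184 with 1 library left out. Genes moved back by the polyphenols numbered 1 without the filter, 5 after rescaling to equal totals, 34 without the Mup genes, 237 adjusted over the genes called under DEHP, and 0 to 78 with 1 library left out. Camera called 16, 12 and 17 lists at the preset correlation and 0 in each comparison with an estimated correlation. Ugt1a6b in DEHP against Control was at 0.27 and at -0.041 after quantile normalization. The lone control and left-out libraries mean fewer samples, and for other differences the cause was not tested.

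Replicate numbers gave no sign of pairing. Same-numbered libraries of different groups had a mean correlation of deviations of -0.0642, with 1 of 9 pairs above 0.1. Other pairs had a mean of 0.0315, with 4 of 18 above 0.1. Deviations sum to 0 within each group, so these means offset each other. With a replicate block, 2271 genes changed in DEHP against Control, 0 in DEHP_GTP against DEHP and 578 in DEHP_GTP against Control. Of 165 calls of named genes, 56 held in all 18 alternatives run for them and 109 were lost in at least 1, among them 108 lost with the lone control. Absolute depth is unknown, so what it limits could not be computed.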

Other observations

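Single genes of other lists also changed under DEHP, although camera called none of these lists. Adjusted p was 0.483 for fatty acid and triglyceride synthesis, 0.163 for gluconeogenesis and glycolysis, 0.0956 for p53 targets, 0.873 for cytokines and chemokines and 0.512 for the acute phase response. Mogat1, an enzyme of triglyceride synthesis, rose by 3.46 (SE 0.20), and Pklr, the liver pyruvate kinase, fell by 1.98 (SE 0.15). Gdf15, a stress-induced cytokine, rose by 1.80 (SE 0.22), Cxcl1, a neutrophil chemokine, by 1.44 (SE 0.18) and Il1rn, the interleukin-1 receptor antagonist, by 1.33 (SE 0.17). Of 26 genes of bile acid synthesis and transport, 10 rose and 2 fell, or 10 and 5 adjusted over the list alone, and camera did not call the list (adjusted p = 0.875). Fry called 6 lists that camera did not, with an adjusted p of 0.00255 for p53 targets, 0.0113 for bile acid synthesis and transport, 0.00144 for arachidonic acid metabolism, 0.0213 for female-biased genes, 0.0309 for lipoproteins and 0.0455 for AhR targets. Fry tests a list against no change and camera against the other genes. Fry placed all 6 upward, the way the median gene also lay (0.12), and was run only on the values as deposited. Whether these calls follow the scaling was not tested. Abcg8, a sterol transporter, rose by 0.81 (SE 0.11), while Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at -1.03 (SE 0.35, adjusted p = 0.0676 by limma) and did not pass.

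The scalings by the median gene and without the Mup genes were added after the data had been seen, and the test of transcript length was written after the results of the gene lists were known. The other tests were written before the values they measure were seen, on patterns found in the same data.

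More genes were higher than lower under DEHP. Transcript length stays open: 73.8% of called genes were higher in the longest of 3 equal groups of genes by transcript length, above a bound of 60%. The share was 89.9% in the shortest, and fold changes fell with length across genes (Spearman correlation -0.248). Since scaling also moves the share of higher genes, this test cannot decide. The fall of the Mup share stays open: rescaling without the Mup genes took the median log2 fold change from 0.12 to -0.061, but the Mup shares alone fix a shift of 0.22 for every other gene, so this test could not have come out otherwise. Library scaling stays open: after centring on the median gene 63.3% were higher, above the bound of 60% set in advance, but that bound was wrong as a test of scaling in general, since quantile normalization gave 52.5% and rescaling without the Mup genes 44.6%. How many genes truly rose or fell therefore cannot be told apart from the choice of scaling.

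Fold changes of DEHP_GTP against DEHP ran opposite to those of DEHP against Control. The covariance of -0.0726 lay below each of 100 simulations, which argues against shared libraries as the whole cause where no group differs. With 1 of the 6 libraries left out, the weakest covariance was -0.0571, also below each simulation. The simulations held no DEHP effect, so they leave out libraries that respond to DEHP with unequal strength. Whether unequal response in the shared libraries or in a single library gives the pattern was therefore not decided. Time of day stays open: with a clock gene score as a covariate, the covariance did not shrink but went to -0.0917, while the simulated range widened to a lowest of -0.116, and 6 of 100 simulations were as low. Of the variance of that score, 69.1% lay between groups, so it cannot be told apart from treatment. The clock score averaged 2.36 ± 0.170 in Control, 1.35 ± 0.567 in DEHP and 2.39 ± 0.346 in DEHP_GTP libraries (SD, n = 3). An effect of the polyphenols is a hypothesis that may account for the pattern, and no single gene passed the test.

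Of 30 male-biased genes 17 fell, 2 rose and 11 were not called under DEHP, with an adjusted p = 0.586 with an estimated correlation, and of 20 female-biased genes 6 rose and 1 fell. With the lone control 4 male-biased genes were called lower, at a median of -1.35 for the list against -1.32. Female animals among the DEHP libraries are argued against by Y-linked genes, whose mean in the lowest DEHP library was 119% of that in the lowest Control library. Reads shared between gene copies are argued against as the whole cause, since the 10 male-biased genes outside multigene families had a median of -0.86, with 6 lower and 0 higher. Lower expression of part of the male-biased genes with the phthalate or its oil may account for the pattern as a hypothesis, and the oil alone was not analysed here.

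The 10 splits of 6 libraries are too few for a share under 0.05. Every split but the real one mixes the groups unevenly and so keeps part of any true difference. The counts of lists as large therefore cannot decide whether the calls would arise in unchanged groups. For genes changed, the real split gave 2654, 0 and 1085 in DEHP against Control, DEHP_GTP against DEHP and DEHP_GTP against Control, and the highest other split 0, 1 and 0, with 1, 10 and 1 splits as large. In DEHP_GTP against DEHP the real split gave 0, so every split was bound to be as large and this count decides nothing. There 1524 genes had an unadjusted limma p below 0.05 in the real split, and at most 1002 in any other. For lists at the preset correlation the real split gave 16, 12 and 17 and the highest other split 16, 17 and 19, with 3, 9 and 3 splits as large, the real one included.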
